A study of Komagataeibacter europaeus with 12 samples.

How the data were processed

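RNA was sequenced from 12 samples of Komagataeibacter europaeus CGMCC 20445, 3 at each of 10, 40, 64 and 88 h of an acetic acid fermentation. Per the labels' protocols, total RNA was checked on agarose gels, by spectrophotometer, by fluorometer and on a Bioanalyzer, and libraries were made with standard Illumina protocols. HTSeq 0.6.1 was used for counting, per the submitters' processing notes. The aligner, its settings, the genome build, the strandedness and any removal of ribosomal RNA are not given in the sources used here. Without a statement on strand, reads from a gene and from an antisense transcript over it cannot be told apart, and overlapping genes are uncertain for the same reason.

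The values used are FPKM, deposited by the authors as 1 table with a column per sample and a line for each of 3532 locus tags with the prefix of strain SRCM101446. The deposited FPKM were checked against coding lengths: FPKM times length in kb sums to 985989 to 994479 per sample, and low values fall on whole multiples of 1 read. The FPKM as deposited are therefore scaled for depth and gene length, with no further scaling between samples. From the size of 1 read, 2580170 to 4439110 assigned reads per sample were worked out. Between 82.0% and 83.2% of the values under 500 reads were whole numbers of reads within 0.02. Depth limits the precision of a single value, since 1 read in a gene of 1 kb is 0.225 to 0.388 FPKM, and reads without molecular identifiers are not independent molecules. Replicates also differed by more than the counting of reads alone would give. Over 2269 genes, chi-square per degree of freedom was 3.72 to 16.3 between replicates of a time, 40 h A apart. For 40 h A against 40 h B and C it was 583 and 635. All 15 ribosomal RNA tags and 750 tags in all are listed at 0 in every sample.

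Symbols and the order of genes came from the RefSeq gene table of assembly ASM217351v1, matched on locus tags. Of the 3532 tags 3312 matched and 723 carried a symbol. No coordinates are printed, because no build is named with the values. The table holds no product names, so gene functions are background to the symbols, and where a symbol occurs more than once the locus tag is given with it. The lengths used are coding lengths.

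Groups, comparisons, gene lists, tests and the rule for naming genes were set before the data were examined. FPKM were analysed as log2(FPKM + 1), for the 2753 genes with FPKM of at least 1 in at least 3 samples. Adding 1 pulls the fold changes of genes near the floor toward 0. A linear model with a mean per time was fitted to all 12 samples with limma 3.58.1 in R 4.3.3, with moderated variances following a trend on mean expression. The comparisons were 40 h versus 10 h, 64 h versus 40 h, 88 h versus 64 h, 64 h versus 10 h and 88 h versus 10 h, together with limma's F test for any difference and a slope on acidity. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. Acidity was compared with exact two-sided permutation tests.

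The 34 gene lists, fixed by symbol, held 534 genes, and 27 lists had at least 3 tested members. Each was tested against the other genes with camera at a preset correlation of 0.01, and again with a correlation estimated from the data. Fry was run beside them. Named genes were the 10 largest rises and 10 largest falls with a symbol in 88 h versus 10 h and the 4 largest of each in the other comparisons, among called genes with mean FPKM of at least 10 and groups that do not overlap. The rule added the 3 members of highest mean FPKM in each list with its called extremes, a set of acetic acid bacterium genes where a symbol allowed it, and the 10 features of highest mean FPKM. The rule left no called gene for falls in 88 h versus 64 h and for either direction in 64 h versus 40 h.

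The fit was tested on simulated data for 88 h versus 10 h with 2753 genes, of which 200 were changed by known folds, 50 at each size. With 12 libraries, 40 h A among them, it recovered 4% of changes of 0.5 on the log2 scale, 22% of changes of 1, 64% of changes of 2 and 78% of changes of 3, with 0 calls among 2553 unchanged genes. With 11 libraries, 40 h A left out, it recovered 54%, 90%, 100% and 100%, with 10 calls among the unchanged genes. The changed genes were drawn from those at about 10 FPKM or more at 10 h, so recovery nearer the floor was not measured. Camera called the 1 list that had been shifted and no other. For that run the genes were drawn independently of each other and 40 h A was left undisturbed. It therefore could not show false list calls from correlated genes or from that library.

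Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 10, median-ratio rescaling, quantile normalization, the replicate letter as a block, variances without a trend, a fit to the 6 samples compared, a 2-fold minimum, an estimated correlation for the lists, time in hours in place of acidity, and each replicate left out in turn. Leaving out 40 h A had been planned for the counts of genes and lists in the comparisons with 40 h, and was added for the other comparisons, the F test and the slope after the data were seen. Array weights, and the removal of 40 h A together with another setting, were also added then. Nothing was removed from the main tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.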

Results

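The transcriptome of Komagataeibacter europaeus CGMCC 20445, an acetic acid bacterium that oxidises ethanol to acetic acid, was measured by RNA sequencing at 4 times of an acetic acid fermentation. The 12 libraries fall into groups of 3, taken at 10, 40, 64 and 88 h and lettered A, B and C. The labels do not say whether the letters stand for separate fermentations, so the spread behind every p-value is the spread between these samples, which may be technical. Expression was given as FPKM (fragments per kilobase of gene, scaled to the reads assigned in each library) for 3532 locus tags of the genome of strain SRCM101446, and 2753 genes were tested. Gene symbols were available for 723 of the tags. The genes for the subunits of the membrane alcohol and aldehyde dehydrogenases, catalase and succinyl-CoA:acetate CoA-transferase carry no symbol in the sources used here and could not be named. Fold changes are given as log2 fold ± standard error, later time over earlier time, and levels as mean FPKM ± SD with n = 3.

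Each library held an estimated 2580170 to 4439110 reads assigned to genes, as worked back from the FPKM steps, and 1 read in a gene of 1 kb stood for 0.225 to 0.388 FPKM. The 10 genes with the most reads took 18.0% of the reads of 40 h library A and 8.79% to 10.5% of the reads in the other 11. That library correlated with the others at r = 0.746 to 0.772 across genes on the log2 scale, against 0.947 to 0.992 among the other 11. Its tRNA genes summed to 1869 FPKM, against 23317 to 39506 FPKM in the rest. GroEL (groL, S101446_02984) stood at 25887 FPKM in 40 h A and at 9363 and 9446 FPKM in 40 h B and C. The first principal component, which parted 40 h A from the rest, held 77.0% of the variance of the 12 libraries, and the first component of the other 11 held 49.0%. All 12 libraries entered the tests, as planned, and the counts of called genes are given again without 40 h A. That had been planned for the comparisons with 40 h and was added for the others after the data were seen, since all tests share the spread estimated over the 12 libraries.

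**Figure D1:**
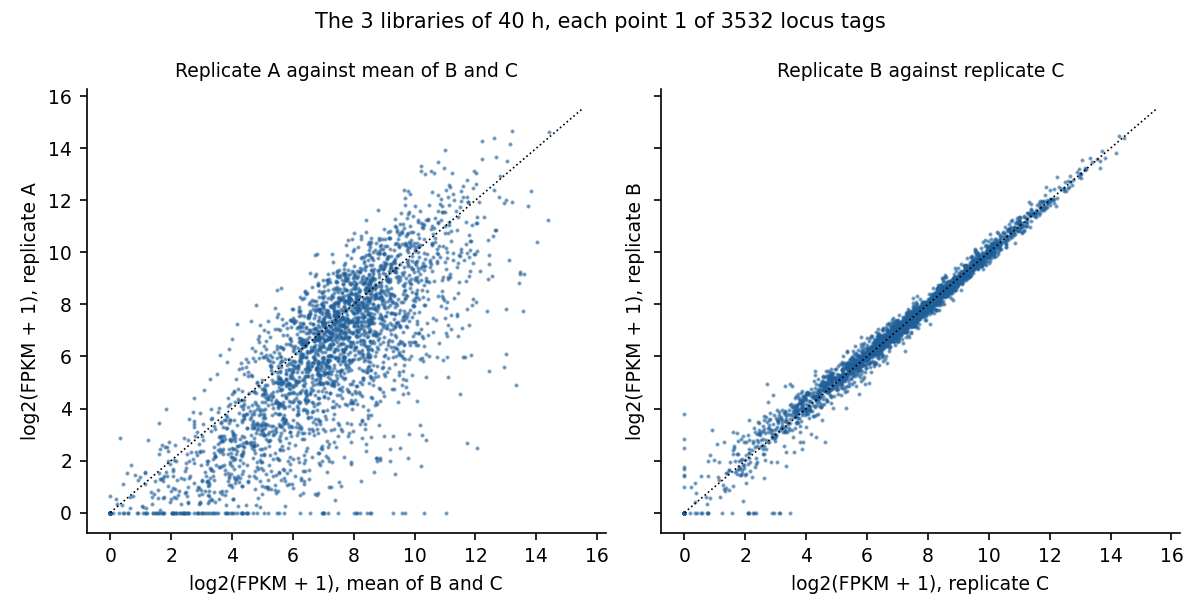
Log2(FPKM + 1) of 40 h library A against the mean of 40 h libraries B and C (left) and of library B against library C (right), with 1 point for each of 3532 locus tags and a dotted line of equality. B and C lie close to the line, while A scatters widely around it, and its highest r with any other library is 0.772.

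Acidity, given for each sample in g per 100 mL, averaged 1.43 ± 0.042 at 10 h, 2.34 ± 0.10 at 40 h, 3.18 ± 0.12 at 64 h and 4.08 ± 0.21 at 88 h (SD, n = 3). The 3 samples of each later time all lay above those of the earlier time. In an exact two-sided permutation test each of the differences, 0.913 from 10 to 40 h, 0.84 from 40 to 64 h, 0.90 from 64 to 88 h and 2.65 from 10 to 88 h, had p = 0.1, the smallest that 3 samples against 3 can give. Acidity and time rise together in this design, so genes that follow one cannot be separated from genes that follow the other.

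**Figure D2:**
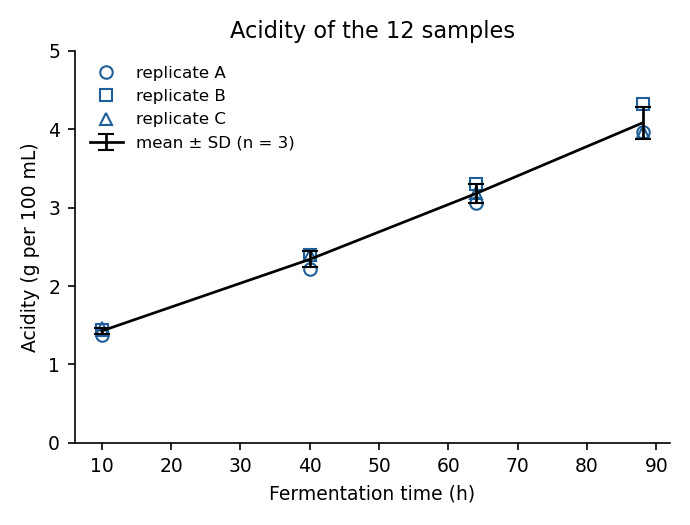
Acidity in g per 100 mL against fermentation time in hours, with 1 point for each of the 12 samples (circle, square and triangle for A, B and C) and a line through the group means with bars of ± 1 SD. The means go from 1.43 at 10 h to 4.08 at 88 h, and the ranges of the 4 times do not overlap.

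Between 10 h and 88 h, the start and the end of the sampled fermentation, the list of tricarboxylic acid cycle genes was called higher at the preset correlation and not at an estimated one. In it 7 of 9 measured members rose and 1 fell, with a median log2 fold of 1.50 (camera adjusted p = 1.93e-05; adjusted p = 0.0617 with an estimated correlation). Citrate synthase gltA (S101446_01074), which joins acetyl-CoA to oxaloacetate, rose from 479 ± 92.6 to 2487 ± 689 FPKM (2.36 ± 0.52, adjusted p = 0.0198). Aconitase acnA (S101446_02412) rose by 1.37 ± 0.25 on the log2 scale, from 1050.5 ± 111 to 2737 ± 490.5 FPKM. The subunits of succinate dehydrogenase, which passes electrons from succinate to ubiquinone, rose together, sdhA by 1.81 ± 0.19, sdhC by 2.14 ± 0.30 and sdhD by 2.22 ± 0.25. The oxoglutarate dehydrogenase component odhB rose by 1.50 ± 0.35 and fumarase fumC by 1.33 ± 0.21. The succinyl-CoA synthetase subunit sucC went the other way (−0.76 ± 0.14, adjusted p = 0.00880), and its partner sucD, at −0.58 ± 0.19, did not pass (adjusted p = 0.112). With 40 h A left out, 7 of the 9 rose and 2 fell, sucC and sucD (adjusted p = 5.51e-04 for sucD).

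Genes of the proton-pumping NADH dehydrogenase (complex I) in 1 of 2 stretches of the genome rose further. The list names 16 genes, of which 6, S101446_00728 to S101446_00733, are listed at 0 in all 12 libraries and were not tested. Of the 10 measured members 7 rose and the other 3 did not pass, with a median log2 fold over the 10 of 3.34 (camera adjusted p = 2.86e-12; adjusted p = 0.00699 with an estimated correlation). The members that rose were nuoF (S101446_01322, 3.93 ± 0.37), nuoG (S101446_01321, 3.86 ± 0.26), nuoH (S101446_01320, 4.06 ± 0.39), nuoI (S101446_01319, 4.01 ± 0.27), nuoK (S101446_01317, 3.28 ± 0.83), nuoL (S101446_01316, 3.19 ± 0.17) and nuoN (S101446_01315, 3.41 ± 0.23). The level of nuoG went from 52.0 ± 16.1 FPKM at 10 h to 130.0 ± 3.02 at 64 h and 757 ± 133 at 88 h. The 3 members that did not pass lie in the other stretch, beside the 6 at 0, and were low throughout: nuoF (S101446_00734) was at 2.14 ± 0.111 FPKM at 10 h and 1.80 ± 1.18 at 88 h, nuoE at 2.21 ± 1.23 and 3.40 ± 1.83, and nuoC at 10.8 ± 0.679 and 14.9 ± 1.07.

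The steepest rise of any tested gene was in the pentose phosphate pathway, which makes NADPH and pentoses. Transketolase tkt (S101446_00743) went from 15.9 ± 1.32 to 1813 ± 452 FPKM (6.72 ± 0.50, adjusted p = 3.24e-05). Ribose-5-phosphate isomerase rpiA (S101446_00749) rose by 4.68 ± 0.28 and glucose-6-phosphate dehydrogenase zwf (S101446_00746) by 4.34 ± 0.65. The 6-phosphogluconate dehydrogenase gene gnd (S101446_00745) rose by 1.77 ± 0.16. The other copies of these genes did not pass: tkt S101446_02552 was at 1489 ± 52.3 FPKM at 10 h and 1538 ± 81.6 at 88 h (0.046 ± 0.35), zwf S101446_02454 at 745 ± 27.7 and 1028 ± 33.1, and rpiA S101446_02559 at 522 ± 20.9 and 554 ± 7.40. Of the 22 measured members of the glycolysis, Entner-Doudoroff and pentose phosphate list, these 4 rose and 1 fell, the Entner-Doudoroff aldolase eda (−0.62 ± 0.16). With 40 h A left out, 9 rose and 4 fell. The median log2 fold of the list was 0.24 and its mean 0.89 (camera adjusted p = 8.51e-04; adjusted p = 0.240 with an estimated correlation). The members of highest mean FPKM besides tkt S101446_02552 were gap (0.13 ± 0.15) and rpe (−0.021 ± 0.15), neither of which passed.

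**Figure D3:**
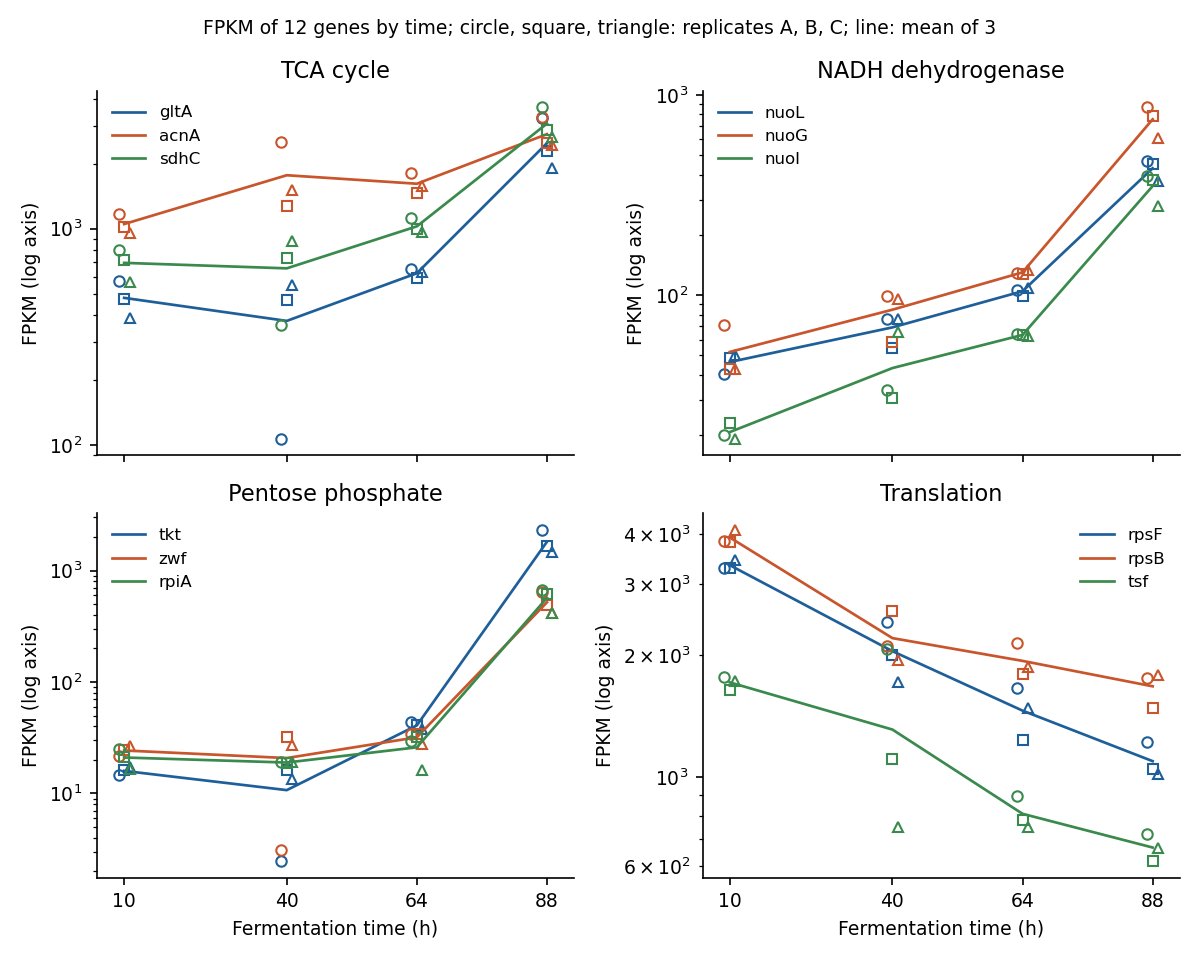
FPKM on a log axis against fermentation time in hours for 12 genes of the tricarboxylic acid cycle, complex I, the pentose phosphate pathway and translation, with 1 symbol per library (circle, square and triangle for A, B and C) and lines through the means of 3. The pentose phosphate gene tkt (S101446_00743) goes from 15.9 FPKM at 10 h to 1813 at 88 h, and the complex I gene nuoG from 52.0 to 757, while rpsF, rpsB and tsf go down; 40 h A lies far from B and C for several genes.

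The lists of ribosomal proteins, translation factors and nucleotide biosynthesis were called lower at 88 h by camera, although most of their members did not pass in limma. Among 51 ribosomal protein genes 8 fell and 43 did not pass (15 fell when adjusted over the list alone), with a median log2 fold of −0.85 (camera adjusted p = 7.70e-10; adjusted p = 0.0240 with an estimated correlation). Without 40 h A, 49 of the 51 fell. The small-subunit genes rpsF (S101446_01458, −1.62 ± 0.17) and rpsB (S101446_00998, −1.23 ± 0.16) and the large-subunit gene rplI (S101446_01456, −1.22 ± 0.23) fell most among those that passed. The most abundant members were rplL (−1.40 ± 0.45), rpsL (−0.87 ± 0.93) and rpsU (−0.0056 ± 0.76), none of which passed. Translation factors and tRNA synthetases had 3 of 33 members lower (22 lower and 3 higher without 40 h A) and a median of −0.40 (camera adjusted p = 0.0191; adjusted p = 0.428 with an estimated correlation). Elongation factor Ts, tsf (S101446_00997), fell by 1.36 ± 0.30, while tuf (−1.03 ± 0.35), infB (−0.093 ± 0.39) and infC (0.22 ± 0.20) did not pass. In nucleotide biosynthesis 5 of 26 members fell (15 lower and 1 higher without 40 h A) and the median was −0.33 (camera adjusted p = 0.0121; adjusted p = 0.0617 with an estimated correlation). The purine gene purD (S101446_02499) fell by 1.15 ± 0.21 and nucleoside diphosphate kinase ndk by 0.91 ± 0.24, and purC (0.087 ± 0.55) and dcd (0.20 ± 0.80) did not pass. Other large falls were in recO (S101446_00996, recombinational repair, −1.93 ± 0.17, adjusted p = 1.12e-04), pth (S101446_02662, peptidyl-tRNA hydrolase, −1.70 ± 0.32), ssuD (S101446_02194, alkanesulfonate monooxygenase, −1.40 ± 0.32), gorA (S101446_02865, glutathione reductase, −1.25 ± 0.31) and queA (S101446_02531, tRNA queuosine synthesis, −1.20 ± 0.23).

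**Figure D4:**
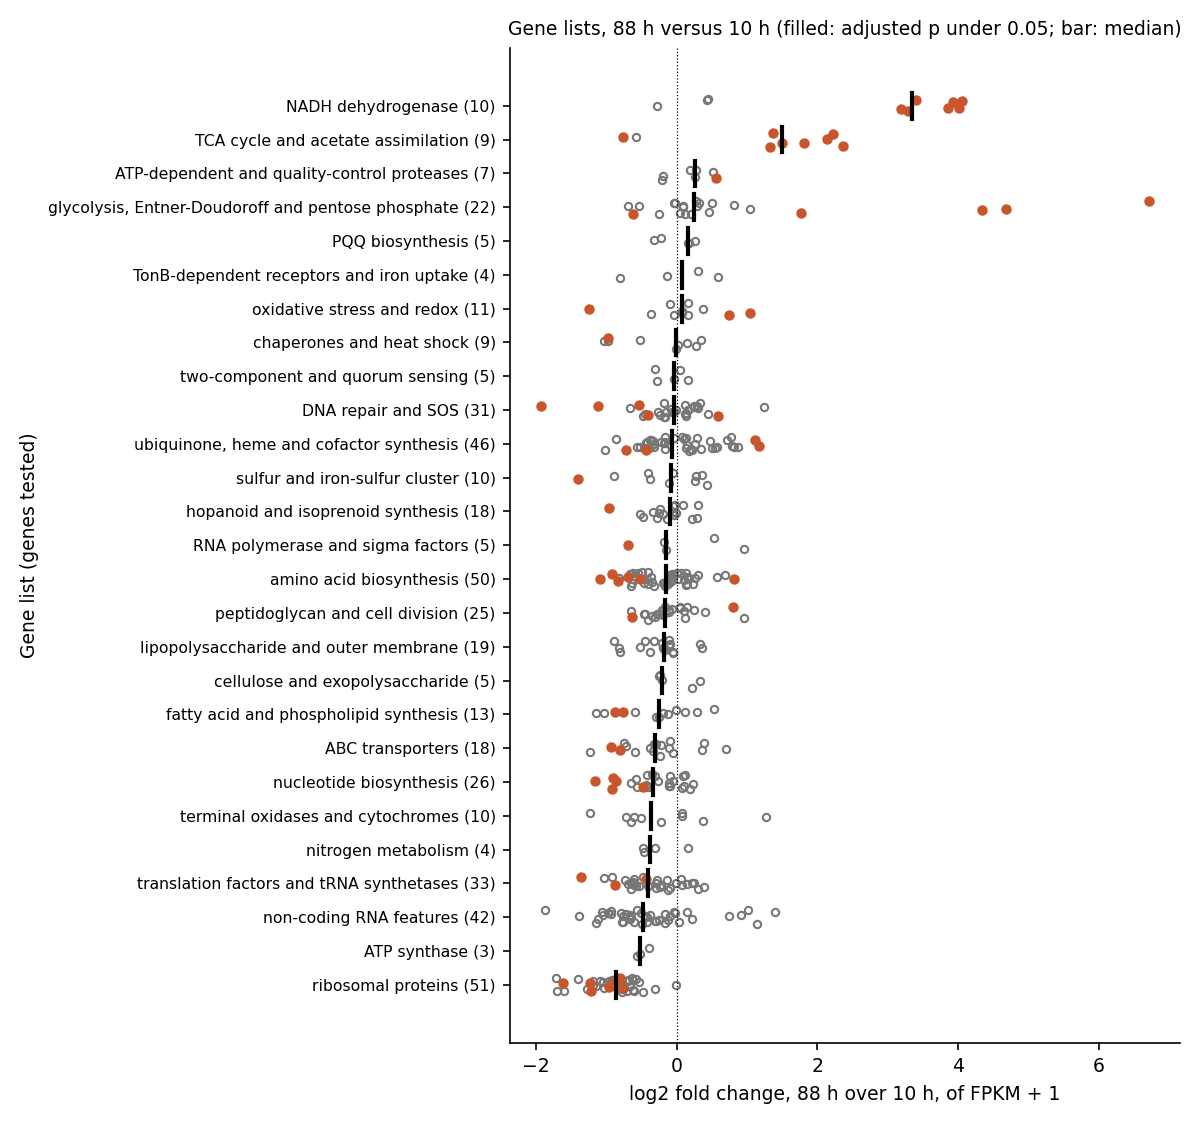
Log2 fold change from 10 h to 88 h of every tested member of the gene lists, with 1 point per gene, filled where the adjusted p is under 0.05, and a bar at each list median. The NADH dehydrogenase median is 3.34 and the tricarboxylic acid cycle median 1.50, while ribosomal proteins have a median of −0.85.

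Altogether 118 genes were higher and 115 lower at 88 h than at 10 h at an adjusted p under 0.05, of which 74 and 33 changed at least 2-fold. Of these 233 genes, 141 have no symbol. Without 40 h A the counts were 526 and 893, with 121 and 96 at least 2-fold, and all 233 were called again in the same direction. Of the genes picked by the naming rule that had not passed, 48 passed once it was left out. Leaving out any 1 of the 6 libraries compared gave 67 to 79 higher and 45 to 62 lower. The values of the 2 times did not overlap in 60.3% of the 2753 genes, against 10% by chance. The median log2 fold of all genes was −0.10, and median-ratio rescaling moved it to 0.0032 and the counts to 150 higher and 79 lower. The 6 lists that passed camera, 3 higher and 3 lower, kept the sign of their medians under that rescaling and under quantile normalization, were called again without 40 h A, and were called in the same direction by fry, a test of whether a list moves one way by itself (adjusted p = 5.01e-07 to 0.0126). They also passed camera after rescaling, where 1 nucleotide gene was lower; with 40 h A left out as well, nucleotide biosynthesis did not pass and non-coding features did. With an estimated correlation and 40 h A left out, none of the 6 passed. The other 21 lists did not pass camera, though fry called 9 of them, each lower. Without 40 h A fry called 13 lists that camera did not call.

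The ethanol oxidation list held 2 measured genes, too few for the list test. The alcohol dehydrogenase gene adhP (S101446_01122) rose by 0.90 ± 0.14, from 2685 ± 179.9 to 5015 ± 202 FPKM (adjusted p = 0.00362), and the aldehyde dehydrogenase gene aldA did not pass (0.74 ± 0.43, adjusted p = 0.411). For synthesis of pyrroloquinoline quinone, the cofactor of the membrane alcohol dehydrogenase, none of the 5 members passed in limma, and 1 was higher without 40 h A (camera adjusted p = 0.873), with pqqB at 0.18 ± 0.58, pqqC at −0.22 ± 0.13 and pqqE at 0.26 ± 0.17. The glycerol-3-phosphate dehydrogenase gene glpD was at −0.26 ± 0.18. Among the terminal oxidases, which reduce oxygen, cyoA (−0.51 ± 0.27), cyoB (−0.60 ± 0.20, adjusted p = 0.117) and cyoD (0.077 ± 0.35) did not pass, and the ATP synthase genes atpA (−0.39 ± 0.21), atpC (−0.56 ± 0.32) and atpD (−0.52 ± 0.22) did not either. When 40 h A was left out, 5 of 10 genes in the oxidase and cytochrome list were lower and 1 higher, and all 3 ATP synthase genes were lower. Camera did not call the ATP synthase list (adjusted p = 0.219), while fry called it lower (adjusted p = 0.00856).

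The stress lists held calls in both directions, and their counts depended on 40 h A. Of 9 chaperone and heat shock genes 1 fell: groES (S101446_02983), the co-chaperonin and the most abundant feature of the data, by 0.97 ± 0.25 (adjusted p = 0.0407). Its partner groL was at −0.98 ± 0.37 and did not pass with all 12 libraries (adjusted p = 0.163), and passed without 40 h A (adjusted p = 2.76e-05). The Hsp70 gene dnaK was at −0.010 ± 0.21 and the disaggregase gene clpB at 0.35 ± 0.29, neither past the threshold. Of 7 protease genes clpA rose by 0.55 ± 0.13, while clpS (−0.19 ± 0.64), ftsH (0.26 ± 0.27) and lon (0.52 ± 0.19) did not pass. In the redox list of 11, 2 rose and 1 fell: superoxide dismutase sodC (S101446_01166) rose by 1.05 ± 0.19, from 211 ± 34.8 to 434 ± 4.08 FPKM, and gorA fell. The peroxiredoxin gene ahpC (0.37 ± 0.41), trxA (−0.038 ± 0.45) and grxD (0.078 ± 0.44) did not pass. Of 31 DNA repair genes 1 rose, recJ (0.58 ± 0.13), and 4 fell, with recA (−0.24 ± 0.16), uvrA (−0.19 ± 0.17) and ssb S101446_02776 (0.14 ± 0.13) not passing. In the fit without 40 h A, 2 chaperone genes were higher and 4 lower, 5 protease genes were higher and 1 lower, 3 redox genes were higher and 2 lower, and 7 DNA repair genes were higher and 8 lower.

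Calls went both ways in the amino acid, peptidoglycan and cofactor lists, and only lower in the fatty acid, hopanoid and RNA polymerase lists. Fry called the amino acid (adjusted p = 2.38e-04), fatty acid (5.23e-06), hopanoid (0.00343) and peptidoglycan (0.0110) lists lower, and camera called none of them. The cofactor (0.914) and RNA polymerase (0.322) lists did not pass fry. Of 50 amino acid genes 5 fell and 1 rose: ilvC, of branched-chain amino acid synthesis, fell by 1.09 ± 0.15, metK, which makes S-adenosylmethionine, fell by 0.91 ± 0.12, and dapA, of lysine synthesis, rose by 0.81 ± 0.15, while hisD S101446_00267 was at −0.64 ± 0.32 (camera adjusted p = 0.0630 for the list). Of 13 fatty acid and phospholipid genes 2 fell, among them plsX (−0.88 ± 0.22), and fabF (−0.30 ± 0.21) and fabZ (−0.20 ± 0.43) did not pass. Of 18 hopanoid and isoprenoid genes ispF fell (−0.96 ± 0.13), and the hopanoid genes hpnH (−0.25 ± 0.13), hpnI (0.31 ± 0.20) and hpnJ (−0.015 ± 0.14) did not pass. Of 25 peptidoglycan and cell division genes mltA fell (−0.63 ± 0.12) and ftsL rose (0.80 ± 0.21), with mraZ (0.96 ± 0.92), pal (−0.45 ± 0.37) and tolQ (−0.20 ± 0.22) not passing. Of 46 cofactor genes 2 rose and 2 fell: lipB, of lipoate attachment, rose by 1.17 ± 0.11 and ribH, of riboflavin synthesis, fell by 0.71 ± 0.16, while hemA (0.77 ± 0.42), hemB (0.57 ± 0.19) and hemC (−0.45 ± 0.28) did not pass. The sigma factor rpoD fell by 0.68 ± 0.14, and rpoH (0.95 ± 0.61) and rpoZ (0.54 ± 0.25) did not pass. With 40 h A left out, 22 amino acid genes were lower and 5 higher, 6 fatty acid genes lower and 1 higher, 7 hopanoid and isoprenoid genes lower and 2 higher, and 10 peptidoglycan genes lower and 3 higher. Of the cofactor genes 18 were then lower and 13 higher, and of 5 RNA polymerase and sigma factor genes 2 were lower and 2 higher.

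In the transport, envelope and regulatory lists the counts also depended on 40 h A. Of 18 genes in the ABC transporter list, which was matched on symbols, 2 fell, among them the phosphate transporter gene pstC S101446_01385 (−0.93 ± 0.17). Its members cydD (−1.23 ± 0.42), ettA (−0.33 ± 0.47) and mlaD (0.70 ± 0.36) did not pass. Of 10 sulfur and iron-sulfur genes ssuD alone passed, with fdxA at −0.88 ± 0.65, cysC at −0.11 ± 0.37 and cysD at −0.052 ± 0.22. In the iron list bfr S101446_00914 (0.30 ± 0.30), feoB (−0.14 ± 0.40) and mbfA (−0.80 ± 0.54) did not pass, nor did lpxA (−0.17 ± 0.11), lpxC (0.36 ± 0.15) and lpxD (−0.056 ± 0.11) of lipopolysaccharide synthesis, or bcsD (−0.24 ± 0.15), galU (0.34 ± 0.21) and pgm (0.22 ± 0.33) of cellulose synthesis. The nitrogen genes glnA (−0.46 ± 0.46), gltB (−0.48 ± 0.16) and ntrX (0.16 ± 0.28), the regulators ntrC (−0.30 ± 0.23) and phoU S101446_02137 (−0.030 ± 0.35), cheB (0.051 ± 0.34) and istB (−0.20 ± 0.36) did not pass. When 40 h A was left out, 10 genes of the ABC transporter list were lower and 1 higher, 6 of 19 lipopolysaccharide genes lower and 1 higher, 3 of 4 nitrogen genes lower, and 4 sulfur genes lower and 3 higher. In the iron list 1 was then lower and 2 higher of 4, in the cellulose list 2 were lower and 2 higher of 5, and of 5 two-component and quorum sensing genes 1 was lower. Of the non-coding features 42 were tested, all of them tRNA genes. None passed in limma with 40 h A, whose tRNA genes summed to 1869 FPKM. Without that library 17 were lower and 1 higher (fry adjusted p = 0.00351, camera adjusted p = 0.0557). The most abundant were S101446_01860 (−0.78 ± 2.4), S101446_01996 (−0.24 ± 0.65) and S101446_02305 (−0.42 ± 0.85). The lists for drug and organic acid efflux, MFS transporters and toxin-antitoxin pairs matched 0 symbols.

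The features of highest mean FPKM over the 12 libraries were groES at 21096 FPKM, S101446_01330 at 18204, S101446_00696 at 18134, S101446_00358 at 15167, pal at 12488, S101446_02179 at 12421, S101446_00695 at 11059, rpsU at 10704, S101446_02093 at 10297 and rpsL at 10281. Of these 10, groES alone passed in 88 h versus 10 h in the fit to all 12 libraries, 40 h A among them. From 10 to 88 h S101446_00696 was at 1.51 ± 0.80, S101446_01330 at −0.68 ± 0.71, S101446_00358 at 0.66 ± 1.8, S101446_02179 at 0.19 ± 1.3, S101446_00695 at −0.042 ± 0.46 and S101446_02093 at −0.15 ± 1.1.

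Between 64 h and 88 h, the last interval, camera called 3 lists higher at the later time, 1 of them on 4 genes. Complex I had 6 of 10 members higher (median 2.12, camera adjusted p = 1.72e-25; adjusted p = 4.95e-04 with an estimated correlation), with nuoF S101446_01322 up by 2.75 ± 0.37. The tricarboxylic acid cycle list had 3 of 9 higher, sdhA, sdhC and sdhD (median 0.82, camera adjusted p = 1.81e-09; adjusted p = 0.0205 with an estimated correlation). In the pentose phosphate pathway tkt S101446_00743 rose by 5.41 ± 0.50 (adjusted p = 3.26e-04), rpiA S101446_00749 by 4.43 ± 0.28, zwf S101446_00746 by 3.96 ± 0.65 and gnd S101446_00745 by 1.86 ± 0.16 (list median 0.011, mean 0.72, camera adjusted p = 3.29e-05; adjusted p = 0.139 with an estimated correlation). Another 5 lists were lower as sets although 0 of their genes passed in limma: ribosomal proteins (median −0.32, camera adjusted p = 5.39e-05; with an estimated correlation adjusted p = 0.0765), translation factors (camera adjusted p = 0.00487; with an estimated correlation adjusted p = 0.279), and nucleotide biosynthesis (camera adjusted p = 0.0367; with an estimated correlation adjusted p = 0.0972), and, passing both ways, amino acid biosynthesis (median −0.16, camera adjusted p = 0.00524; with an estimated correlation adjusted p = 0.0408) and peptidoglycan and cell division (median −0.20, camera adjusted p = 0.00518; with an estimated correlation adjusted p = 0.0458).

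In all, 35 genes were higher at 88 h than at 64 h, 33 of them at least 2-fold, and 0 were lower by limma; at an unadjusted p under 0.05 the counts were 81 and 45. Of the 35, 20 have no symbol. Without 40 h A, 171 were higher and 183 lower, 52 and 1 of them at least 2-fold, and all 35 were called again in the same direction. Of the 5 lower lists, ribosomal proteins then had 14 genes lower, translation factors 8, amino acid biosynthesis 8 (and 2 higher), nucleotide biosynthesis 5 and peptidoglycan genes 6 (and 1 higher), and 7 tricarboxylic acid cycle genes were higher and 1 lower. The 8 lists were also called without 40 h A, with the non-coding features as another lower list, and complex I was then the 1 list to pass with an estimated correlation. The lower side depends on the scaling. With median-ratio rescaling of the 12 libraries 39 genes were higher and 0 lower, and translation factors, amino acid biosynthesis and nucleotide biosynthesis no longer passed (camera adjusted p = 0.0562, 0.0739 and 0.0881; medians −0.11, −0.11 and −0.10). Rescaling without 40 h A gave 201 higher and 54 lower, with 4 ribosomal protein genes lower, 2 of translation factors, 2 of amino acid biosynthesis (3 higher), 0 of nucleotide biosynthesis and 1 of peptidoglycan (2 higher). Of the 8 lists amino acid biosynthesis alone did not pass there (camera adjusted p = 0.0514). Leaving out any 1 of the 6 libraries gave 20 to 27 higher and 0 lower. Groups did not overlap in 33.2% of genes, against 10% by chance.

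From 10 h to 64 h, complex I was already higher, with 4 of 10 members past the threshold: nuoI S101446_01319 (1.57 ± 0.27), nuoG S101446_01321 (1.35 ± 0.26), nuoN (1.21 ± 0.23) and nuoL S101446_01316 (1.16 ± 0.17). With 40 h A left out, 7 passed. The median of this list was 1.19 (camera adjusted p = 9.63e-06; adjusted p = 0.0566 with an estimated correlation). Ribosomal proteins were lower, with 3 of 51 past the threshold and 42 without 40 h A (median −0.52, camera adjusted p = 4.26e-07; adjusted p = 0.0566 with an estimated correlation). The largest falls among genes with a symbol were recO (−1.45 ± 0.17), rpsF (−1.21 ± 0.17), rpsB (−1.02 ± 0.16) and the adenosine deaminase gene add (−1.01 ± 0.23). In all 43 genes were higher and 42 lower, 18 and 15 of them at least 2-fold. Without 40 h A the counts were 502 and 619, with 50 and 49 at least 2-fold, and all 85 were called again in the same direction; leaving out 1 of the 6 libraries compared gave 4 to 16 higher and 1 to 9 lower. Median-ratio rescaling gave 33 higher and 16 lower, and groups did not overlap in 52.0% of genes, against 10% by chance.

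From 10 h to 40 h, the interval in which acidity went from 1.43 to 2.34 g per 100 mL, the largest rises among genes with a symbol were in lpdA S101446_02462, the dihydrolipoyl dehydrogenase (1.07 ± 0.21), hemB, of heme synthesis (1.02 ± 0.19), nuoN (1.00 ± 0.23) and the protease gene lon (0.92 ± 0.19). The largest falls were in ssuD (−1.48 ± 0.32), panC, of pantothenate synthesis (−1.42 ± 0.33), queA (−1.31 ± 0.23) and pstC S101446_01385 (−1.13 ± 0.17). The comparison called 42 genes higher and 76 lower, 12 and 32 of them at least 2-fold. Without 40 h A the counts were 415 and 672, with 30 and 71 at least 2-fold, and all 118 were called again in the same direction. Leaving out another library gave 2 to 82 higher and 0 to 281 lower, with 2 and 0 without 10 h B and again without 10 h C. The median log2 fold of all genes was −0.42 with 40 h A and −0.10 without it. Median-ratio rescaling brought the median to −0.027 and the counts to 76 and 50, and quantile normalization to 0.061, with 88 higher and 59 lower. Groups did not overlap in 36.1% of genes, against 10% by chance.

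Of the lists, 4 were higher and 1 lower at 40 h, and none passed with an estimated correlation. Proteases (median 0.70, camera adjusted p = 0.00164, and adjusted p = 0.441 with an estimated correlation) and peptidoglycan genes (median 0.047, camera adjusted p = 0.0121, and adjusted p = 0.164 with an estimated correlation) were called higher with and without 40 h A. These calls are relative to the other genes, and the median of all genes was −0.42 with that library. In limma 2 of 7 proteases and 1 of 25 peptidoglycan genes were higher and 0 lower. Without 40 h A 4 proteases were higher, and 9 peptidoglycan genes were higher and 1 lower. The protease median was then 0.24 and the peptidoglycan median 0.18 (camera adjusted p = 0.548 and 0.487 with an estimated correlation). Complex I (median 0.26, camera adjusted p = 0.0181; adjusted p = 0.441 with an estimated correlation) did not pass once that library was left out (median 0.43, camera adjusted p = 0.115). Translation factors were called higher (camera adjusted p = 0.0181, and adjusted p = 0.499 with an estimated correlation) with a median of 0.031 and a mean of −0.015. Without 40 h A they lay in the other direction with no call by camera (median −0.13, camera adjusted p = 0.648). In limma 13 members were then lower and 5 higher, and fry passed (adjusted p = 0.0163). Non-coding features were lower, with a median of −2.09 that became −0.51 without 40 h A (camera adjusted p = 0.0231; adjusted p = 0.853 with an estimated correlation). Ribosomal proteins had a median of −0.61 and were called lower without 40 h A (camera adjusted p = 1.49e-09; adjusted p = 0.548 with an estimated correlation), where 42 of 51 fell. After rescaling of the 12 libraries complex I did not pass, while ribosomal proteins (lower), amino acid biosynthesis and DNA repair (higher) did.

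From 40 h to 64 h a single gene passed, S101446_02546, which has no symbol and is named here although chosen after its values were seen. It rose from 25.0 ± 1.02 to 135 ± 10.1 FPKM (2.38 ± 0.19, adjusted p = 5.23e-04), and went on to 689 ± 153 FPKM at 88 h. No gene was lower by limma (0 of 2753); at an unadjusted p under 0.05, 232 genes were higher and 37 lower. Without 40 h A, 37 were higher and 21 lower, 7 and 0 of them at least 2-fold, with S101446_02546 among the former. The median log2 fold of all genes was 0.38 with 40 h A and 0.05 without it, and median-ratio rescaling moved it to 0.029. Groups did not overlap in 20.2% of genes, against 10% by chance.

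Of the lists, 2 were higher and 11 lower at 64 h than at 40 h, and with an estimated correlation none was called. Complex I was higher (median 0.62, camera adjusted p = 0.0305; adjusted p = 0.154 with an estimated correlation), and so were the non-coding features (median 2.07, and 0.30 without 40 h A; camera adjusted p = 0.00107; adjusted p = 0.582 with an estimated correlation). Translation factors were lower (median −0.22, and −0.058 without 40 h A; camera adjusted p = 7.71e-08; adjusted p = 0.103 with an estimated correlation). Peptidoglycan genes, with a median of 0.059, were lower relative to the other genes, whose median was higher still (camera adjusted p = 0.00549; adjusted p = 0.103 with an estimated correlation). Their median was −0.064 without 40 h A and −0.30 after median-ratio rescaling of all 12 libraries. These 4 lists also passed without 40 h A at the preset correlation, and none did at an estimated one (adjusted p = 0.653 for each). The other 9 lower lists did not: chaperones, ribosomal proteins, proteases, RNA polymerase, nucleotide synthesis, DNA repair, fatty acid synthesis, amino acid synthesis and ABC transporters (camera adjusted p = 0.00232 to 0.0327; adjusted p = 0.103 to 0.154 with an estimated correlation). The medians of ribosomal proteins (0.084), DNA repair (0.028), amino acid synthesis (0.029) and ABC transporters (0.026) were above 0, though below that of all genes. The medians of these 9 lists without 40 h A lay between −0.067 and 0.048. After rescaling of the 12 libraries complex I, ribosomal proteins, proteases, RNA polymerase and fatty acid synthesis did not pass and hopanoid synthesis did (lower).

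Over all 4 times, 180 genes differed between any of them in limma's F test, and 1646 did so without 40 h A. Against acidity as a continuous measure 99 genes rose and 85 fell, and 435 and 687 did so without 40 h A. Leaving out all 4 libraries of letter A gave 1610 genes in the F test, while leaving out those of B or C gave 11 and 19. For the slope on acidity the same removals gave 284 rising and 441 falling without A, 0 and 0 without B, and 0 and 1 without C.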

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

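Counts of genes are given as higher and lower, in the order 40 h versus 10 h, 64 h versus 40 h, 88 h versus 64 h, 64 h versus 10 h and 88 h versus 10 h. Array weights and every setting without 40 h A beyond the planned comparisons with 40 h were chosen after the data were seen. Array weights gave 40 h A, whose spread enters every variance, a weight of 0.0073, and the counts became 497 and 925, 176 and 58, 202 and 328, 633 and 817, and 594 and 1025, with 1984 genes in the F test and slopes on acidity of 518 and 841. Leaving out 1 library at a time, 40 h A included, gave ranges of 2 to 415 and 0 to 672, 1 to 37 and 0 to 21, 20 to 171 and 0 to 183, 4 to 502 and 1 to 619, and 67 to 526 and 45 to 893, with the upper end in each case without 40 h A and the 2 and 0 of 40 h versus 10 h without 10 h B or 10 h C. The F test ranged from 11 (without letter B) to 1646, and the slope from 0 (without B or C) to 435 and from 0 (without B) to 687. Lists past the threshold ranged from 4 to 8 in 40 h versus 10 h, 4 to 14 in 64 h versus 40 h and 2 to 4 in 64 h versus 10 h. With only the 6 samples compared, the counts were 1 and 0 in 40 h versus 10 h, 0 higher in 64 h versus 40 h, 149 and 89 in 88 h versus 64 h, 503 and 605 in 64 h versus 10 h, and 525 and 877 in 88 h versus 10 h.

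Median-ratio rescaling gave 76 and 50 in 40 h versus 10 h, 16 lower in 64 h versus 10 h and 5 lists in 88 h versus 64 h; with 40 h A removed as well it gave 565 and 513, 27 and 26, 201 and 54, 606 and 540, and 724 and 692, an F count of 1619, slopes of 555 and 552, and 4 lists in 64 h versus 40 h. Quantile normalization gave 88 higher in 40 h versus 10 h, 189 and 176 in 88 h versus 10 h, an F count of 303 and slopes of 161 and 189. A pseudocount of 5 gave 117 lower in 40 h versus 10 h. A 2-fold minimum gave 12 and 32, 18 and 15 in 64 h versus 10 h, and 74 and 33 in 88 h versus 10 h, fewer by construction. With an estimated correlation 0, 0, 4, 0 and 2 lists passed, and 0, 0, 1, 0 and 0 with 40 h A removed as well. The deviations from the time means showed no clear pairing by letter. Of 18 pairs with the same letter they correlated at −0.127 to 0.147, 2 of them over 0.1, and 3 of 12 samples were most like one of their own letter. The 40 h mean includes 40 h A, so pairs with 40 h say little. With 40 h A removed, the block called more genes in each comparison and the F test than no block, and fewer in the slope. In 64 h versus 40 h it gave 157 and 78 against 37 and 21, so pairing by letter is left open. With the replicate block the counts were 13 and 34 in 40 h versus 10 h and 22 and 14 in 64 h versus 10 h; the replicate block with 40 h A removed gave 415 and 731, 157 and 78, 180 and 236, 527 and 638, and 548 and 923, an F count of 1723 and slopes of 409 and 648. The cause was not tested except where stated. A pseudocount of 0.1, no filter on low values, a mean FPKM of at least 10, variances without a trend and time in hours in place of acidity kept each count they were run on within 1.5 times of that reported.

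Of the 141 values of named genes, 93 kept direction and side of the threshold without 40 h A and 48 more passed it; under the replicate block 124 were kept and 17 no longer passed; under median-ratio rescaling 103 were kept, 27 no longer passed, 1 more passed and 10 reversed, all in 88 h versus 10 h and none past the threshold: infB 0.012, lpxD 0.049, cysD 0.053, S101446_00695 0.063, trxA 0.067, phoU S101446_02137 0.074, rpe 0.084, hpnJ 0.090, dnaK 0.095 and rpsU 0.099. Leaving out 1 library, hpnJ ranged from −0.043 to 0.028, dnaK from −0.051 to 0.040, rpe from −0.11 to 0.069, rpsU from −0.20 to 0.099, phoU S101446_02137 from −0.074 to 0.053 and cyoD from −0.054 to 0.20. Leaving out another library was run on the named genes of the comparisons with its time, called or not. It ended 25 to 29 calls among 137 values for a 10 h library and 13 to 18 among 125 for an 88 h library. For a 64 h library it ended 5 to 8 among 12, and for 40 h C 7 among 8, while none ended for 40 h B. Depth limits the genes near 0.225 to 0.388 FPKM, the value of 1 read in 1 kb.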

Other observations

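All tests in this part were chosen after the results were seen. Several of the largest changes lie in genes without a symbol, chosen here from their values. S101446_00552 stood at 269 ± 2.97 FPKM at 10 h, 2061 ± 192 at 40 h, 2763 ± 362 at 64 h and 4148 ± 284 at 88 h (3.94 ± 0.14 from 10 to 88 h), and its 40 h value in library A, 2055 FPKM, lies between those of B and C. The neighbours S101446_03221 to S101446_03225 were called higher by 40 h: S101446_03225 went from 32.6 ± 3.80 FPKM at 10 h to 139.6 ± 29.8 at 40 h and stood at 173 ± 17.3 at 88 h (2.37 ± 0.18). In the opposite direction, S101446_00181 went from 364 ± 46.6 FPKM at 10 h to 72.0 ± 50.1 at 40 h (98.9 without library A) and 58.0 ± 2.74 at 88 h (−2.62 ± 0.53). Its neighbour S101446_00182 (−2.37 ± 0.28), S101446_03353 (−2.39 ± 0.47) and S101446_03366 (−2.24 ± 0.44) also fell.

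Many genes that rose from 10 to 88 h lie side by side: 28 of them form 4 runs of at least 4 neighbouring locus tags. The runs are S101446_00742 to S101446_00746 (5 genes with tkt, gnd and zwf, log2 fold 1.77 to 6.72), S101446_01314 to S101446_01327 (14 genes with 7 of the nuo genes, 1.90 to 4.06), S101446_02449 to S101446_02452 (4 genes with sdhA, sdhC and sdhD, 1.81 to 2.22) and S101446_03221 to S101446_03225 (5 genes, 2.14 to 3.03). All 28 were still higher after median-ratio rescaling, the lowest at 1.87. That cannot test scaling as a cause, because the rescaling raised the median log2 fold of all genes from −0.10 to 0.0032 and so could not end these calls. The median log2 fold of 3.23 was at least 3.01 with any 1 of the 6 libraries left out. The genes had been chosen as called in these same libraries. A rise set by 1 library was therefore unlikely to be among them, and the result is no independent test. Within a run the genes' deviations from their time means over 11 libraries had a median r of 0.712, against 0.330 between runs (permutation p = 0.00030, 2 of 10000 permutations as high). Most of the pairs within runs come from the run of 14 genes. Transcription of the genes of a run together is therefore a candidate explanation mainly for that run, and the shorter runs were not tested apart. What drives the runs with time or acidity stays untested, since both rise together.

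The library 40 h A differs from 40 h B and C with an SD of 1.84 on the log2 scale over 2411 genes, against 0.147 to 0.247 for the other 11 libraries. Gene length is not the whole cause, since an SD of 1.76 stayed after the trend on length was removed, and a swap with another library of the series is excluded, since its highest r was 0.772 and the lowest among the other 11 was 0.947. Reads from another strain or species are a candidate explanation only if they make up nearly all of the library. A smaller share would still leave native reads in well-covered genes. Of 2143 protein-coding genes with at least 100 predicted reads, 6 are listed at 0 in it and none of the 6 in any of the other 11. Among them are S101446_00323 (1094 reads predicted, and 1329.8 and 1191 FPKM in B and C) and S101446_00752. Among genes of at least 900 bp the median log2 difference was 0.015 for the 363 with a symbol and −0.80 for the 838 without, a gap that was at most 0.048 in the other 11. A library made up of foreign reads cannot be told here from a sample from outside the series. No biological explanation was tested, and foreign reads were not looked for in a genome.

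Of the 3532 locus tags, 750 are listed at 0 in all 12 libraries, among them 586 protein-coding tags. Reads shared between identical copies account for few of them, since 3.92% of those 586 share a protein accession with another tag. All 23 protein-coding tags with a shared accession are at 0, however. A 0 for a repeated gene therefore need not mean absence or no expression. Stretches of the reference genome absent from the sequenced strain are a candidate explanation: of the 563 protein-coding tags at 0 without a shared accession, 69.6% lie in runs of at least 5 consecutive such tags, against at most 3.73% in 10000 random placements among 3174 protein-coding tags. The other 164 tags at 0, with the 15 of ribosomal RNA, did not enter. The longest of the 35 runs, S101446_00762 to S101446_00798, holds 37 tags, and 50.2% of the 273 plasmid tags are at 0 against 16.6% of the 3039 chromosomal tags. A genome of the sequenced strain was not analysed here, and no biological explanation was tested.

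Other groupings of the 6 samples of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. For genes past the threshold, 1 of 10, the real one, gave as many in each comparison: 118 genes for 40 h versus 10 h, 1 for 64 h versus 40 h, 35 for 88 h versus 64 h, 85 for 64 h versus 10 h and 233 for 88 h versus 10 h, and the highest other grouping gave 0 in each. For gene lists, 6 of 10 groupings gave as many for 40 h versus 10 h (real 5, highest other 13), 1 for 64 h versus 40 h (13 and 12), 1 for 88 h versus 64 h (8 and 5), 6 for 64 h versus 10 h (2 and 6) and 3 for 88 h versus 10 h (6 and 6). Groupings with 13 lists against a real 5, or 6 against a real 2, point to a structure of the samples or to a list test that calls too many lists at its preset correlation. The same limit holds for 88 h versus 10 h, where another grouping reached the real 6. It also holds for 64 h versus 40 h, where another gave 12 against 13. In the real grouping 0 lists passed with an estimated correlation in 40 h versus 10 h, 64 h versus 40 h and 64 h versus 10 h. Those calls therefore depended on the preset value. In 88 h versus 10 h 2 of the 6 passed with an estimated correlation, and 0 did so without 40 h A. The other groupings were not run with an estimated correlation, and a structure of the samples was not tested. Over all 12 samples, 1 of 100 groupings, the real one, gave as many genes as the F test's 180 (highest other 32). Likewise 1 of 100 orders of the acidity values, the real one, gave as many as the slope's 184 (highest other 0). These draws take the 12 samples as independent, which the labels do not state. If samples of a time share a source, the draws cannot separate time from that source, so chance is not excluded.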
